A study of Mus musculus with 2 samples.

How the data were processed

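The samples were 2 ATAC-seq libraries of mouse megakaryocyte primary cells, which formed 1 group, with the sample labels as the only source of grouping. Per the labels, the peaks were called on the mouse genome build mm10, from filtered alignments of each sample and a list of excluded regions. The peak caller, the aligner and their versions were not given in the sources used here. Of the lists the authors deposited, those used were, for each sample, a list of pseudoreplicated peaks and a list thresholded on the irreproducible discovery rate (IDR), both called on that sample, and for the series a list of replicated peaks and a conservative IDR list, both called on the pooled samples. In the deposited lists, column 7 holds the fold enrichment of a peak over its local background, a ratio, taken from the peak format since no file header defines it. The deposited columns 8 and 9 hold the −log10 p-value and the −log10 q-value of each peak, and column 10 the position of its summit. The deposited lists of each sample that were used held no peak with a p-value above 0.00997. No scaling between samples is stated, and fold enrichments were compared between the samples as deposited. All columns of values were assigned to a sample or to the pooled series, with 0 left unmapped. No read counts were available, so the depth per sample is unknown, and no interval that would need it was computed.

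The replicates are separate biosamples with 1 donor record. Every p-value over regions or genes therefore describes these 2 samples, and SDs over n = 2 measure the spread between them. No comparison between groups was possible. Peaks of a list that overlapped by at least 1 bp were merged, with the highest fold enrichment and its summit kept, and regions on chromosomes 1 to 19 and X were used. A shared region was the union of regions that overlapped between the replicates by at least 1 bp. The overlap was set against 100 random placements of the regions of replicate 2, on the same chromosomes and outside assembly gaps. Regions were classed as promoter where any part of them lay within 1 kb of any GENCODE M21 transcript start. The others were classed by their summit as exon, intron or intergenic, and distal means any class but promoter.

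A protein-coding gene (21755 in all) had an open promoter where a shared region lay within 500 bp of any of its transcript starts, which was so for 13004 genes (59.8%). Lists of genes were written before the data were examined, as were the comparisons and the alternatives not named as added. The 18 lists were megakaryocyte and platelet surface and granule genes, megakaryocyte and erythroid transcription factors, platelet signalling, proplatelet cytoskeleton and granule biogenesis, thrombopoietin and cytokine signalling, erythroid, stem and progenitor cell, neutrophil, monocyte and macrophage, mast cell, basophil and eosinophil, B cell, T and NK cell, endothelial, mesenchymal stromal, hepatocyte, neuronal, cell cycle and endomitosis, and housekeeping genes. Of 375 listed symbols, 373 were matched to the annotation, while Ahsp and Clec7a were not analysed here. No gene was in more than 1 list. Promoters of a list were compared with those of all other genes by two-sided Fisher exact tests. Distal regions within 50 kb of the start were counted per gene and compared with 100000 random lists matched on quintiles of promoter CpG content and of gene length, by two-sided permutation tests whose smallest p is 2e-05. Genes of the random lists were drawn singly. Neighbours within a list whose windows overlap, such as Cd9 and Vwf, were not reproduced in them, so the matched range may be too narrow. Adjustment was by Benjamini-Hochberg over the 18 lists, with a threshold of 0.05. Named genes were, for each list, the 3 members with the highest mean fold enrichment at the promoter and the members without a shared promoter region, at most the first 6 in alphabetical order, together with the 5 members of the megakaryocyte and platelet and of the transcription factor list with the most distal regions (and any tied with the last), the 10 genes nearest to most distal regions, and the 10 strongest distal and promoter regions. Some genes that this rule would name are not used here.

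The 19 motifs were consensus patterns searched on both strands within 100 bp of the summits of distal regions, with windows 1 kb to each side as background, by two-sided Fisher exact tests adjusted over 19 motifs. Shifts of lists between the replicates were placed among 10000 matched random lists. Alternatives were the IDR lists of each sample, the replicated-peaks and conservative lists of the series, 50% reciprocal overlap, summits within 100 bp, peaks of at least 4-fold enrichment, equal numbers of regions, −log10 p in place of fold enrichment, other windows, the 5′ end as the only start of a gene, other backgrounds, and each replicate left out. On simulated data of 20000 genes, 4% of 200 unchanged lists had p under 0.05 in the Fisher test and as many in the permutation test. For the Fisher test these lists were drawn evenly over all genes, and for the permutation test from genes with high simulated counts. The simulation so does not cover the Fisher test on lists that differ from other genes in promoter CpG content or gene length, as the lists used here do. Of 100 lists with 95% of members open, and of 100 with a 2-fold higher count, 100% were recovered. Smaller effects were not simulated, so the power to detect them is unknown. A simulated ratio of 2 was returned as 2.00. In simulated sequences a motif planted in 30% was found in 30.0%, while a motif that was not planted had a ratio of 0.552 on 16 and 29 occurrences (exact p = 0.0718). In 200 further pairs of sets with nothing planted, the GATA, octamer and STAT motifs had p under 0.05 in 2.5%, 3% and 4.5% of pairs, with lowest ratios of 0.940, 0.556 and 0.316. These sequences were random and do not carry the base composition of the genome. Searches for mitochondrial and repeated sequence used BLAST+ 2.17.0. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.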

Results

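Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in primary mouse megakaryocytes, the bone marrow cells that release platelets. The series held 1 group of 2 biological replicates labelled adult male C57BL/6J, with 50000 cells in each sample. Both replicates carry the same donor record, and the label of replicate 2 alone lists sequencers. There was no other cell type or treatment, so the questions were where chromatin was open, how far the replicates matched, and which genes and sequence motifs lay at the open regions. The files gave peaks and no read counts, so the depth of each sample is unknown, and a region missing from a list was not detected at that depth. Replicate 1 had 108778 listed peaks, which merged into 79823 regions with a median width of 359 bp. Replicate 2 had 114523 listed peaks, merging into 81732 regions with a median width of 392 bp. The regions covered 1.38% of the genome in replicate 1 and 1.51% in replicate 2, and the median fold enrichment over background was 6.65 and 7.01. Values of single regions below are mean fold enrichments ± SD (n = 2 replicates), and a shared region is one found in both replicates.

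The replicates had 69539 regions in common on chromosomes 1 to 19 and X. These included 89.3% of the regions of replicate 1 and 86.2% of those of replicate 2, whereas random placement of the regions of replicate 2 put a mean of 2.88% of them on a region of replicate 1 (100 placements). The overlap covered 31.2 Mb, and the Jaccard index of the covered bases was 0.731. Across shared regions, which are not independent replicates, fold enrichment correlated with Spearman's rho of 0.928 and Pearson's r of 0.927. The log2 ratio of replicate 2 to replicate 1 had a median of 0.05 and an SD of 0.24, and 96.4% of shared regions lay within 1.5-fold. Regions found in 1 replicate only numbered 8512 in replicate 1 and 11257 in replicate 2. They were the weaker ones, with median fold enrichments of 4.01 and 4.19, against 7.30 and 7.74 at shared regions.

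**Figure D1:**
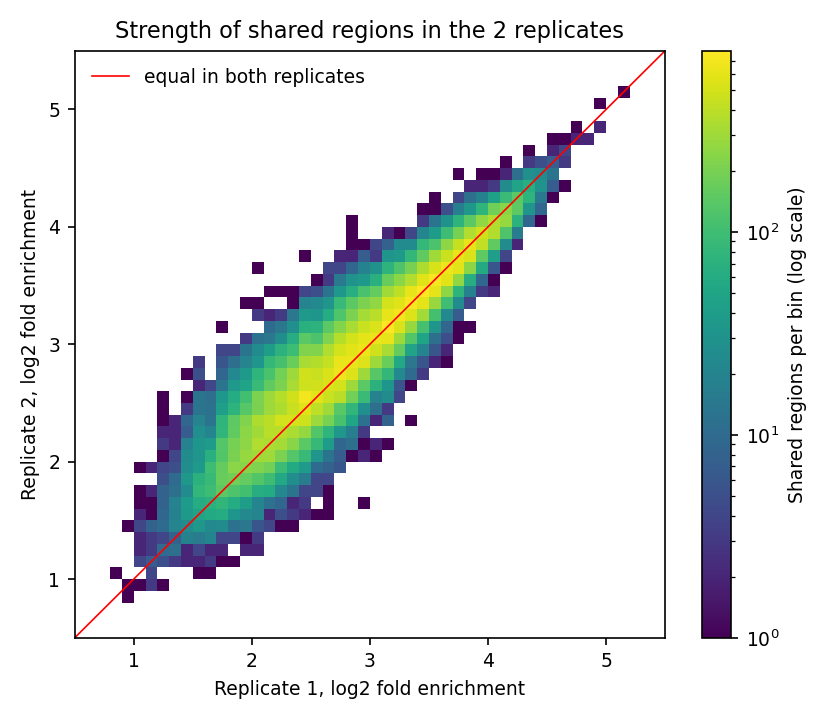
Fold enrichment of each shared region in replicate 1 (horizontal axis, log2) against replicate 2 (vertical axis, log2), with colour for the number of regions per bin. The 69539 regions lie along the diagonal with a rho of 0.928.

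Promoters were strongly represented. Of the shared regions, 20819 (29.9%) had some part within 1 kb of an annotated transcript start. The other shared regions, placed by their summits, lay in introns (25280, 36.4%), between genes (20741, 29.8%) and in exons (2699, 3.88%). Random placement of the same regions put 7.82% at promoters (SD 0.105) and 49.6% between genes. Promoter regions had a median fold enrichment of 8.92, compared with 6.97 in introns and 7.34 between genes. The highest value near the start of a protein-coding gene was at Pnpt1, which encodes a mitochondrial RNA exonuclease (24.3 ± 0.716, chromosome 11, 29130063 to 29131318). Tbc1d10a, a Rab GTPase regulator, followed with 24 ± 0.241, then Gpatch4, a nucleolar protein, with 23.7 ± 0.623, Snrnp48 with 23.3 ± 0.783 and the splicing factor Prpf8 with 22.9 ± 0.110. Starts of non-coding genes and pseudogenes held the other 5 of the 10 highest, led by 2610005L07Rik (29.2 ± 1.85) and Gm21769 (28.3 ± 1.53) on chromosome 8. Promoter regions were not searched for mitochondrial or repeated sequence. These 2 regions start at 20424212 and 20122126, and a distal region at 20550028 on chromosome 8 had 4 other copies in the genome. Shared regions were more often at promoters than regions of 1 replicate, of which 17.7% were (odds ratio 1.99, 95% interval 1.91 to 2.07, two-sided Fisher exact p = 7.97e-272 over 69539 and 19769 regions). The test took no account of width or strength. Shared regions were unions, with a median width of 462 bp, and regions of 1 replicate were weaker. The share at promoters moved between 25.8% and 39.5% with the class window and the peak list.

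Of the 10 strongest distal regions, the highest lay 13.0 kb from the start of Abcb11, which encodes the bile salt export pump (35.7 ± 0.490, chromosome 2, 69355475 to 69355727). The next was in an intron nearest to Rtl10, a retrotransposon-derived gene (31.7 ± 1.18), followed by regions nearest to Nxph1 (29.4 ± 0.689), G6pd2 (27.8 ± 1.01), Sfpq (27.0 ± 1.31), Pak3 (26.9 ± 0.453), Gm21119 (26.2 ± 0.191), Zfp960 (25.9 ± 0.828), Galc (25.8 ± 0.325) and Zfp677 (25.1 ± 0.194). The regions near Abcb11, Nxph1, G6pd2 and Galc matched mitochondrial DNA over at least 100 bases, and the region near Gm21119 had 4 other copies in the genome.

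Promoters of megakaryocyte genes were open in part. Among the 30 surface and granule genes of megakaryocytes and platelets, 17 (56.7%) had a shared region within 500 bp of a transcript start. Itga2b, the alpha chain of the platelet fibrinogen receptor, had the highest value (13.5 ± 0.584, chromosome 11, 102466935 to 102467590), followed by Cd226, an adhesion receptor (11.1 ± 1.4), and Nbeal2, needed for alpha granules (10.1 ± 0.913). These 3 regions lay at annotated starts inside the genes, 2.53, 20.1 and 8.37 kb from the 5′ end, as did the strongest region of 7 of the 17 genes. Clec1b, the podoplanin receptor, Gp6, the collagen receptor, and Gp1ba, Gp1bb, Gp5 and Gp9, of the von Willebrand factor receptor, had none, nor did 7 more, which include the tubulin Tubb1 (named after its value was seen). Of these 13 genes, 3 had a promoter region in 1 replicate and 10 in neither. A difference from the 59.8% of all other genes was not called (odds ratio 0.87, two-sided Fisher exact p = 0.714 adjusted over 18 lists), and the share was 60.0% in replicate 1 and 63.3% in replicate 2. The direction turned against lists matched on promoter CpG content and gene length (45.9% matched, adjusted permutation p = 0.316), with the replicated-peaks list, without replicate 1 and with a 1-kb window, none of them called.

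The lists of transcription factors and of signalling, cytoskeleton and granule biogenesis genes were open at most promoters. With no other cell type in the series, whether these promoters are open in megakaryocytes in particular was not tested. Of 20 megakaryocyte and erythroid transcription factors, 19 (95%) had a shared promoter region (odds ratio 8.76, adjusted exact p = 0.00249), with the highest values at Mef2c, a MADS-box factor (15.2 ± 0.923), the adaptor Ldb1 (14.1 ± 0.567) and Ets1 (13.6 ± 0.970). Those regions lay at internal starts, 129, 5.35 and 59.3 kb from the 5′ end of the gene, and so did the strongest region of 11 of the 19 factors. Erg, an ETS factor of stem cells and megakaryocytes, had one in replicate 1 alone. Platelet signalling genes reached 90.9% (20 of 22, adjusted exact p = 0.00492), led by the small GTPase Rap1b (13.7 ± 0.281), the thrombin receptor F2r (13.6 ± 1.20) and the kinase Syk (13.2 ± 0.938), while the prostanoid receptors Ptgir and Tbxa2r had a region in replicate 2 alone. Proplatelet cytoskeleton and granule genes reached 95.5% (21 of 22, adjusted exact p = 0.000979), led by the formin Diaph1 (15.8 ± 0.553), the vesicle-sorting gene Vps33b (15.8 ± 0.384) and Was (15.2 ± 0.180), with the myosin light chain Myl9 the exception. Each of the 20 thrombopoietin and cytokine signalling genes had a shared region (adjusted exact p = 0.000176), with high values at the adaptor Grb2 (21.2 ± 0.375) and the transcription factor Stat5a (14.5 ± 0.543). The regions of Rap1b, Syk, Grb2 and Stat5a were also at starts other than the 5′ end. Against lists matched on promoter CpG content and gene length the gaps were smaller but passed, with 65.8% matched for the transcription factors (adjusted permutation p = 0.00375), 61.3% for platelet signalling (p = 0.00144), 77.3% for proplatelet genes (p = 0.0473) and 76.5% for thrombopoietin and cytokine signalling (p = 0.00696). The transcription factor call ended with the IDR-thresholded lists of each sample (odds ratio 1.98, adjusted exact p = 0.200) and with the 5′ end of the gene as its only start (2.36, adjusted p = 0.111).

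Neutrophil and monocyte genes were open at most promoters too. Of 21 neutrophil genes, 19 (90.5%) had a shared promoter region (odds ratio 5.26, Fisher exact p = 0.00624 adjusted), with the highest values at the collagenase Mmp8 (11.8 ± 0.482), the iron-binding granule protein gene Ltf (8.91 ± 0.217) and the G-CSF receptor Csf3r (8.73 ± 0.629). Elane, the elastase of primary granules, and the formyl peptide receptor Fpr1 had none. Of 20 monocyte and macrophage genes, 17 (85.0%) had one (odds ratio 3.37, adjusted exact p = 0.0396), led by the receptor kinase Mertk (14.1 ± 0.363), Adgre1, which encodes F4/80 (12.2 ± 0.174), and Irf8 (11.3 ± 0.537), whereas the complement genes C1qa and C1qb and the scavenger receptor Marco had none. Against random lists matched on promoter CpG content and gene length, the shares stood further out, with 25.5% matched for the neutrophil list (permutation p = 0.00018 adjusted) and 38.1% for the monocyte list (p = 0.00018). The neutrophil call against all genes ended with the IDR-thresholded lists (odds ratio 2.12, adjusted exact p = 0.149), the conservative list of the series (2.87, 0.0611) and peaks of at least 4-fold enrichment (2.78, 0.0730). The monocyte call ended without replicate 2 (odds ratio 3.21, adjusted exact p = 0.0596), with the replicated-peaks list (adjusted p = 0.0909), a 1-kb window (0.0661) and the 5′ end (0.111).

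The remaining blood lineages were not called against all other genes. Erythroid genes had 20 of 27 promoters open (74.1%, adjusted exact p = 0.217), with Bpgm, a red-cell phosphoglycerate enzyme (14.8 ± 0.0518), the haem enzyme Fech (11.8 ± 0.303) and Hemgn (9.98 ± 0.931) highest. The haem enzyme Alas2, Aqp1, Car1, Cldn13, the factor Klf1, Rhag and the anion exchanger Slc4a1 (named after its value was seen) had none, and the list passed against matched lists (42.8% matched, adjusted permutation p = 0.0012), with the replicated-peaks list (adjusted exact p = 0.0101) and without replicate 1 (adjusted p = 0.0458). Its odds ratio was below 1, without a call, with the IDR-thresholded lists (0.456, adjusted exact p = 0.0726), the conservative list and the 5′ end. Stem and progenitor genes had 17 of 22 (77.3%, adjusted exact p = 0.176), with the receptor Flt3 (14.2 ± 0.709), Fgd5 (13.2 ± 0.202) and Mllt3 (9.52 ± 0.0308) highest and none at Hoxa5, Ly6a, Mecom, Slamf1 and Tek (68.0% in matched lists, adjusted permutation p = 0.487). Mast cell, basophil and eosinophil genes had 8 of 15 (53.3%, adjusted exact p = 0.645), led by the histamine enzyme Hdc (9.06 ± 0.160), Enpp3 (8.65 ± 1.34) and the IgE receptor chain Fcer1a (8.08 ± 0.192), with none at Cma1, Cpa3, Mcpt4, Mrgprb2, Ms4a2 and Prss34. Matching on CpG content and gene length together turned that direction (20.2% matched, odds ratio 4.50, adjusted permutation p = 0.00702). B cell genes had 9 of 19 (47.4%, adjusted exact p = 0.419), with Vpreb1, a surrogate light chain (18 ± 0.899), Cd22 (12.8 ± 0.0770) and Il7r highest and none at Blk, Cd79a, Dntt, Fcer2a and Igll1. T and NK cell genes had 10 of 20 (50%, adjusted exact p = 0.419), with the T cell receptor chain Cd3d (14.7 ± 0.232), the kinase Lck (13.1 ± 0.172) and Cd5 (12.9 ± 2.30) highest and none at Bcl11b, Cd3e, Cd3g, Cd4, Cd8a and Cd8b1. The values of Fech, Hemgn, Fgd5, Enpp3, Cd22, Cd3d and Lck came from starts other than the 5′ end. Against matched lists the B cell and T and NK cell shares were the higher ones (36.1% and 42.8% matched, adjusted permutation p = 0.457 and 0.615), while the T and NK cell list and the mast cell list were called depleted with the IDR-thresholded lists (adjusted exact p = 0.0243 and 0.00646), and the T and NK cell list also with the conservative list (0.0315).

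Hepatocyte and neuronal genes less often had a promoter region than other genes, and each housekeeping gene had one. None of 20 hepatocyte genes had a shared promoter region (Fisher exact p = 2.19e-07 adjusted), among them Alb, Afm, Ahsg, Ambp and Apoa1, which encode plasma proteins. Neuronal genes had 5 of 20 (25%, adjusted exact p = 0.00496), with Syn1 (18.5 ± 0.0629), Dlx1 (8.41 ± 0.231) and Grin1 (6.85 ± 0.371) highest and none at Camk2a, Dcx, Gad1, Gad2, Gria1 and Kcna1. The neuronal call ended with the replicated-peaks list (adjusted exact p = 0.0648). Endothelial genes had 5 of 15 (33.3%, adjusted exact p = 0.0918), led by the cadherin Cdh5 (14.5 ± 0.0816), Aplnr (8.49 ± 0.575) and Sox17 (7.03 ± 1.99), with none at Cldn5, Emcn, Kdr, Nos3, Ptprb and Ramp2. Mesenchymal stromal genes had 5 of 16 (31.3%, adjusted exact p = 0.0614), with the collagen Col1a1 (12.2 ± 0.456), Acta2 (10.6 ± 0.418) and Pdgfra (7.22 ± 0.377) highest and none at Adipoq, Bglap, Col1a2, Col3a1, Cxcl12 and Dcn. The mesenchymal list passed without replicate 1 (adjusted exact p = 0.0311), without replicate 2 (0.0388), with the conservative list (0.0208) and with the 5′ end (0.00061), but against matched lists it was far from a call (40.7% matched, adjusted permutation p = 0.615). The endothelial list passed with the IDR-thresholded lists (adjusted exact p = 0.00646), the conservative list (0.0302), reciprocal overlap (0.0301) and the 5′ end (0.0173), and narrowly missed against matched lists (59.2% matched, adjusted permutation p = 0.0550). Each of the 20 cell cycle genes (adjusted exact p = 0.000176) and 24 housekeeping genes (adjusted p = 5.95e-05) had a shared region, with the cytokinesis factor Ect2 at 17.3 ± 1.91, Birc5 at 16.5 ± 0.467, the cyclin Ccnb1 at 15.6 ± 0.125, the retromer gene Vps29 at 18.9 ± 0.951, the proteasome gene Psmb2 at 18.1 ± 0.640 and Hprt at 18.1 ± 0.181. Against matched lists the calls of the hepatocyte (31.3% matched, adjusted permutation p = 0.00234), neuronal (60.4%, p = 0.00234), cell cycle (83.3%, p = 0.0473) and housekeeping lists (81.0%, p = 0.00696) passed too. The values of Dlx1, Grin1, Cdh5, Aplnr, Col1a1, Acta2 and Pdgfra came from starts other than the 5′ end.

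**Figure D2:**
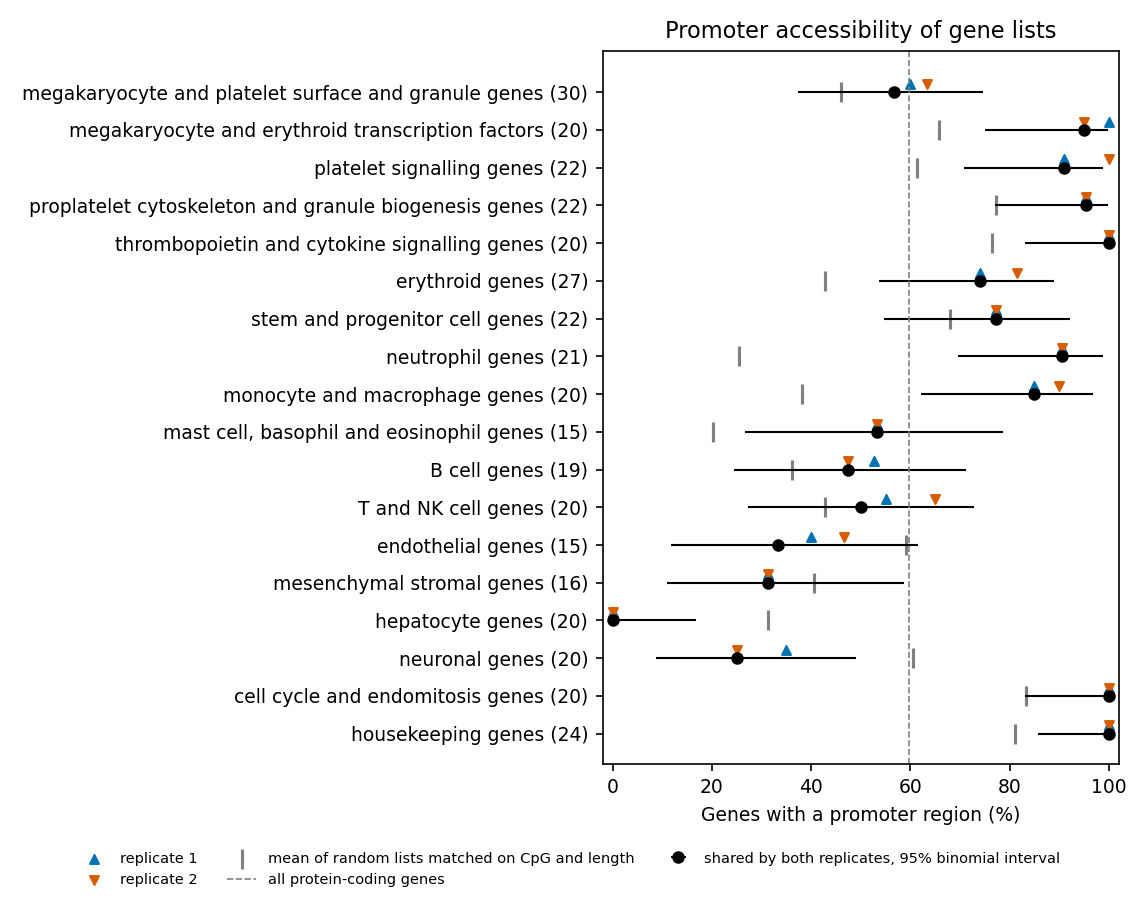
Percent of the genes of each list with a region at the promoter (horizontal axis) for the 18 lists (vertical axis), with both replicates, the shared regions with their 95% Clopper-Pearson interval, and the 59.8% of all protein-coding genes. The neutrophil list stands at 90.5% and the megakaryocyte and platelet list at 56.7%.

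Distal regions, more than 1 kb from any start, were counted within 50 kb of each gene start. The blood transcription factor Fli1 had 14, followed by Etv6 and Runx1 with 12 each Myb with 11, and Ets1, Lmo2, Tal1 and the GATA1 cofactor Zfpm1 with 9 each. Among surface and granule genes, Clec1b, the integrin chain Itgb3 and P-selectin (Selp) had 9 each, and Cd9, Nbeal2 and Vwf had 8. Neutrophil genes had a mean of 7.48 regions per gene, against 2.27 in matched random lists, a ratio of 3.30 (permutation p = 0.00012 adjusted over 18 lists, from the smallest unadjusted p of 2e-05). Monocyte and macrophage genes had 6.60 against 2.61 (ratio 2.53, permutation p = 0.000144), platelet signalling genes 7.09 against 2.93 (2.42, p = 0.00012), thrombopoietin and cytokine signalling genes 7.55 against 3.43 (2.20, p = 0.00012) and transcription factors 6.60 against 3.17 (2.08, p = 0.000144). Surface and granule genes had 4.0 against 2.76, a ratio of 1.45, and missed the threshold after adjustment (unadjusted permutation p = 0.0345, adjusted 0.0620). They passed it with each replicate left out (ratios 1.47 and 1.55), with the replicated-peaks list and with a 100-kb window (1.56 in each). Ratios above 1 were also called for housekeeping genes (5.29 against 3.51, permutation p = 0.0140), cell cycle genes (5.20 against 3.50, p = 0.0314) and proplatelet genes (5.09 against 3.45, p = 0.0372), each of which missed the threshold under at least 1 alternative. Neuronal genes had fewer than matched lists (1.00 against 3.09, ratio 0.32, permutation p = 0.0006). The other 8 lists were not called. They were mast cell, basophil and eosinophil (ratio 1.67, adjusted permutation p = 0.116), T and NK cell (1.48, p = 0.10), B cell (1.28, p = 0.388), erythroid (1.19, p = 0.462), mesenchymal (1.07, p = 0.816), stem and progenitor (1.06, p = 0.816), endothelial (1.04, p = 0.876) and hepatocyte genes (0.79, p = 0.477).

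**Figure D3:**
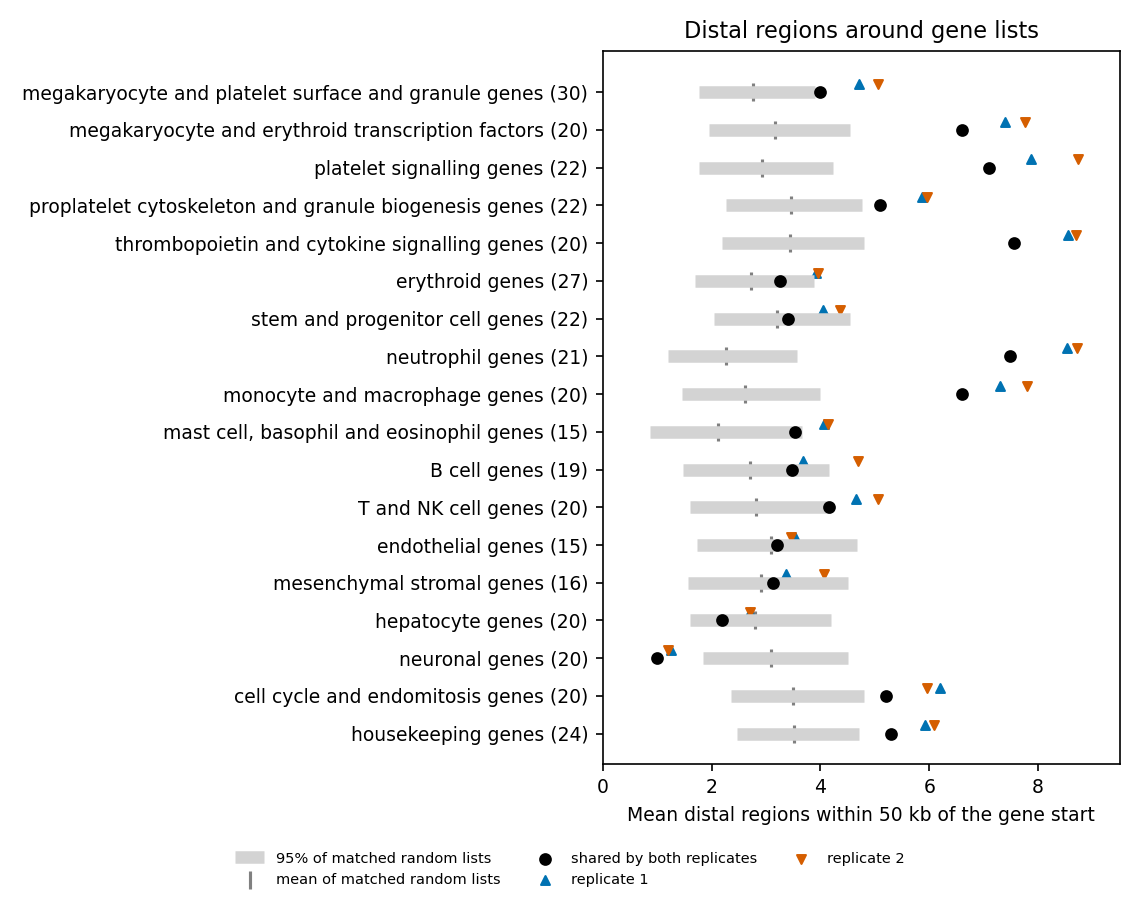
Mean number of shared distal regions within 50 kb per gene (horizontal axis) for the 18 lists (vertical axis), with both replicates and the mean and central 95% of 100000 random lists matched on promoter CpG content and gene length. The neutrophil list stands at 7.48 and the megakaryocyte and platelet list at 4.0, just above its matched range, which ends at 3.90.

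Around Itgb3, which encodes the beta chain of the fibrinogen receptor, 14 shared regions lay between 104558000 and 104658000 on chromosome 11. The promoter region, from 104607914 to 104608588, had a value of 7.62 ± 0.655. The strongest region of the locus was an intronic one in the neighbouring gene Myl4 (15.7 ± 0.380, 104590016 to 104590592), followed by one in an intron of Itgb3 (12.2 ± 0.361, 104647170 to 104647988). Over all genes, the most distal regions were nearest to the adhesion receptor Adgrl2 (62), then the transcriptional regulators Cited2 (54), Lmo4 (49) and Zfp608 (49), Id2, Maf and the neuropilin Nrp1 (47 each), Rab3c (46), Foxp1 (45) and Tgfbr2 (43). These counts were not tested and grow with the space around a gene.

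**Figure D4:**
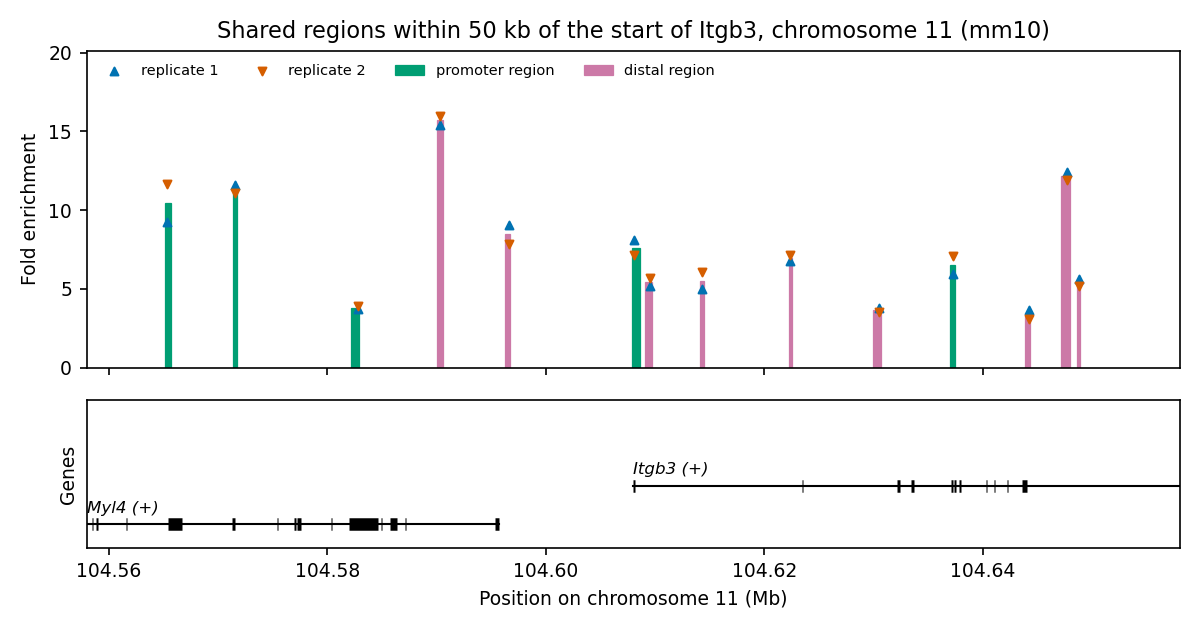
Fold enrichment (vertical axis) of the 14 shared regions at Itgb3 along chromosome 11 (horizontal axis, position on mm10), with bars at the mean of both replicates, a point for each replicate, and gene models beneath. The tallest bar, 15.7, lies in Myl4.

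The summits of the 48720 distal regions were searched for 19 sequence motifs, with windows 1 kb to each side as background. The motif of CTCF, the insulator protein, was the most enriched (7.0% of summits against 0.0876% of background, a ratio of 79.9; its p was too small to be represented). The motif of PU.1, a factor of myeloid and B cells, had a ratio of 54.3 (0.844% of summits, Fisher exact p = 1.37e-164 adjusted over 19 motifs). ETS motifs had 8.44 (6.02% of summits), NF-E2/MAF, bound by the platelet factor NF-E2, 4.94 (exact p = 3.09e-88), C/EBP, bound by granulocyte and monocyte factors, 4.53 (p = 1.30e-230) and RUNX 2.91 (6.66% of summits). AP-1 had a ratio of 2.44, KLF/SP 1.95, NRF1 3.56 (exact p = 0.000176), MEF2 1.5 (p = 1.66e-06), E-box 1.21, STAT 1.21 (p = 0.00855), MEIS/TGIF 1.20 (p = 0.00445), SRF 1.17 (p = 0.00412) and REST 11.1 on 6 occurrences (p = 0.00963). The plain GATA motif was less frequent at summits, with 25.7% against 31.9% (ratio 0.804, 95% interval 0.790 to 0.819, exact p = 1.61e-131), and stayed so against windows matched on GC content (0.951, p = 4.93e-06). The GATA/E-box composite, bound by GATA1 with TAL1, was enriched at 1.39 (exact p = 1.44e-08), but not with the IDR-thresholded lists, where its ratio was 0.984 (p = 0.889). The octamer motif was also less frequent (0.751, exact p = 3.87e-07), and HNF1, a liver motif, was not called (0.617, p = 0.245). The ratios of REST, STAT, MEF2, MEIS/TGIF, SRF and NRF1 each missed the threshold under at least 1 alternative.

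**Figure D5:**
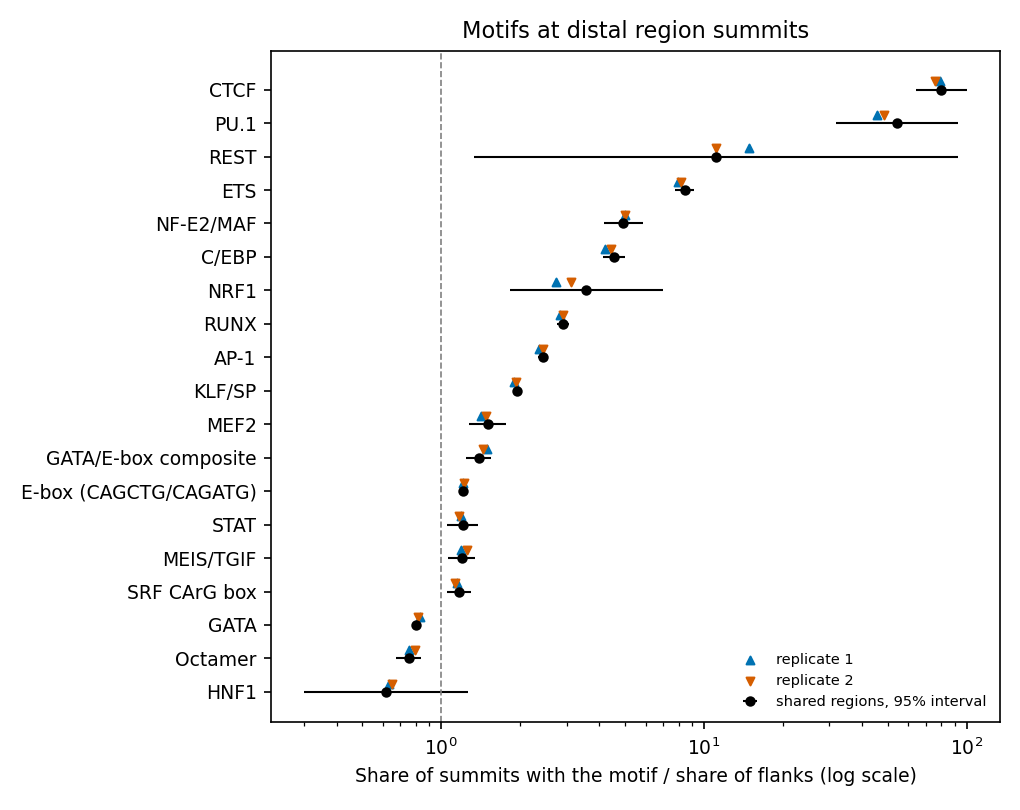
Ratio of motif frequency at distal summits to that in the windows to each side (log scale) for 19 motifs, with 95% intervals and both replicates. CTCF stands at 79.9 and PU.1 at 54.3, while GATA lies at 0.804.

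Between the replicates, no list of genes lay outside the limits set by random lists. The mean log2 ratio of replicate 2 to replicate 1 lay in the central 95% of 10000 random lists matched on fold enrichment for each of the 18 lists. The mast cell, basophil and eosinophil list was lowest (percentile 2.55), then the neutrophil list (4.24), and the T and NK cell list was highest (88.7). With −log10 p in place of fold enrichment, the neutrophil list (percentile 2.17) and the mast cell list (1.90) fell outside these limits, as did the neuronal list (1.90) with the IDR-thresholded lists.

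Along the chromosomes, chromosome 11 had the most shared regions per Mb (38.3), followed by 19 (36.1) and 17 (34.6), and chromosome 14 had the fewest of the autosomes (22.4). Chromosome X had 9.47 per Mb against 28.4 on the autosomes, a ratio of 0.334. The replicates gave 11.0 and 11.3 regions per Mb on X, a spread far below that gap. The median fold enrichment on X was not lower (7.10 and 7.68, against 6.64 and 6.99 on the autosomes). It covers called regions only, so it says nothing on depth. The densest window of 100 kb held 25 shared regions on chromosome 13, from 23500001 to 23600000, where 15 histone genes lie. Windows with 23 regions lay at Lrrfip1 on chromosome 1, at Rcsd1, Creg1 and Cd247 on chromosome 1, and on chromosome 8 from 126800001 in a stretch without protein-coding genes. The other 6 of the 10 densest held 21 or 22 regions and lay at Sfi1 and Drg1 and at B3gnt2 on chromosome 11, Ifitm3 on chromosome 7, Ier5 on chromosome 1, and Ckap4 and Os9 on chromosome 10.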

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

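The test of promoter CpG content and gene length, the search for mitochondrial matches and the direct tests between lists were chosen only after the result was seen. The comparisons left out chromosome Y, where 20 of the 23 regions of replicate 1 overlapped one of the 25 regions of replicate 2, a signal in data that no comparison used. The samples are labelled male, and the median fold enrichment of these regions was 5.71 in replicate 1 and 6.58 in replicate 2.

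Neutrophil and monocyte genes stood above the surface and granule genes of megakaryocytes and platelets. With the expectation from matched genes removed, the neutrophil list exceeded the megakaryocyte list by 54.1 percentage points at promoters (permutation p = 8e-05 adjusted over 4 tests) and by 3.96 distal regions per gene (p = 6e-05). The monocyte list exceeded it by 36.1 points (permutation p = 0.00803) and 2.75 regions (p = 0.00952), whereas for erythroid genes the difference of 20.4 points (p = 0.0921) and of -0.71 regions (p = 0.379) missed the threshold. Without matching, Fisher exact tests of the promoter shares against the megakaryocyte list gave p = 0.0123 for neutrophil genes and 0.0619 for monocyte genes. The monocyte difference at promoters (85.0% against 56.7%) thus missed the threshold there. The matching and the kind of test both changed, so the lost call cannot be assigned to either. Promoter CpG content and gene length were excluded as the whole cause, since 90.5% of neutrophil promoters were open and the matched range ended at 42.9%. Median fold enrichment at the open promoters was 6.10 for the neutrophil list, 7.65 for the monocyte list and 7.62 for the megakaryocyte list.

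Cells of the granulocyte and monocyte lineage in the samples may account for it. A further list of 30 genes of that lineage, none from the first lists and written before its values were seen, had 96.7% of promoters open (matched range 20% to 50%, permutation p = 2e-05, the smallest possible) and 6.77 distal regions per gene against 2.69. Granule genes of the first neutrophil list, picked after their values were seen, included Ltf at 8.91, Camp at 8.30, Lcn2 at 7.63, S100a8 at 7.58, S100a9 at 7.52 and Mpo at 7.30. Ngp was at 4.91, Prtn3 at 4.70, Mmp9 at 3.85 and Ctsg at 3.69, and Elane had no promoter region in either replicate. The values of Mpo, Prtn3 and Mmp9 came from starts other than the 5′ end. Members of a list must lie on both sides of its own median, here 6.10, so this spread says nothing about cells of that lineage. The labels name no sort or gate that would remove such cells. Open myeloid regions in megakaryocytes themselves, or in progenitors, would give the same result, and with 1 group and no other cell type no biological explanation was tested.

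Libraries without megakaryocytes, through a wrong label, could not be excluded. A further list of 23 megakaryocyte genes had 3.09 distal regions per gene against 3.2 in matched lists (range 2.04 to 4.48, permutation p = 0.922) and 69.6% of promoters open against 64.9% (p = 0.793), which is the outcome written in advance for this explanation. It was judged open, and not as borne out, only after that value was seen, because the first megakaryocyte list lay above its own matched range (4.0 against an upper limit of 3.90, unadjusted permutation p = 0.0345, adjusted 0.0620). That list was not called, and its ratio of 1.45 was below those of T and NK cell (1.48) and mast cell, basophil and eosinophil genes (1.67). Those lists were not called either and lay inside their matched ranges, and the other lists without a call had lower ratios. The first list therefore does not show that megakaryocytes were present. The further granulocyte and monocyte list exceeded the further megakaryocyte list by 56.8 points and 4.17 distal regions (permutation p = 4e-05 for each, adjusted from the smallest p of 1e-05).

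Of the 10 strongest distal regions, 3 lay far from genes, at 941.6 kb or more from the nearest protein-coding start, while the other 7 lay at 5.55 to 64.7 kb, around the median of 30.4 kb over all distal regions. Reads of mitochondrial DNA placed on nuclear copies may explain those 3 and the strongest region, since 4 of the 10 strongest matched mitochondrial DNA over at least 100 bases, against 5 of 48710 others (Fisher exact p = 1.13e-13). The matches had 100% identity over 129 bases near Abcb11, 99.7% over 365 bases near Galc, 97.9% over 383 near G6pd2 and 95.8% over 311 near Nxph1. Sequence with several copies in the genome explains few of the others, as 1 of the 10 strongest without such a match had another copy, against 3 of 200 other distal regions (exact p = 0.178). No biological explanation was tested.

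Chromosome X had fewer regions per Mb than the autosomes. Lower depth on the single X of males was predicted to weigh least on strong regions. Among the strongest quartile the ratio was 0.444, above the 0.334 of all regions. It was below the 0.668 of gene density by more than the replicate SD of 0.0191, the outcome written in advance against lower depth. However, the quartile was set by fold enrichment among called regions, which lower depth may itself reduce. Depth is also unknown, so the test cannot exclude lower depth as the whole cause. Fewer genes and CpG-rich promoters were excluded as the whole cause, since 41.5% of 948 X genes had an open promoter and matched autosomal genes had 48.0% to 53.1%. Lower depth, as the whole cause or a part, and a part from gene content remain open, and no biological explanation was tested.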

How the results depend on the processing

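The alternative without distal regions that match mitochondrial DNA was chosen after seeing the data, and it gave 9 lists called for distal regions, as did the original setting. Of 493 values of lists and motifs under alternatives, 420 kept their direction and their side of the threshold, 28 lost a call, 19 gained one and 26 reversed, of which 24 were called under neither setting. The counts of lists enriched at promoters, lists called for distal regions and motifs enriched stayed within 1.5-fold under each alternative run. With the IDR lists of each sample, shared regions numbered 37034 in place of 69539, the rank correlation between replicates was 0.925, the promoter share 39.5%, lists depleted at promoters 5 in place of 2, lists shifted between replicates 1 in place of 0, the X to autosome ratio 0.323, the odds ratio of transcription factor promoters 1.98 and the ratio of the GATA/E-box composite 0.984, a reversal. With the conservative list, the promoter share was 31.7% and 5 lists were depleted, and with the replicated-peaks list these were 26.5% and 1, while the distal ratio of surface and granule genes rose to 1.56. Windows of 500 bp and 2 kb gave promoter shares of 25.8% and 36.0%, and a 100-kb window gave that distal ratio as 1.56. With the 5′ end as the only start, 4 lists were depleted and the transcription factor odds ratio was 2.36. The rank correlation between replicates was 0.928 with reciprocal overlap, 0.913 for peaks of at least 4-fold, 0.926 with equal numbers of regions and 0.942 with −log10 p, which also shifted 2 lists between replicates. The shared percentage of replicate 1 was 83.6 with reciprocal overlap, 84.7 with summits within 100 bp and 92.0 for peaks of at least 4-fold. Matching on CpG content and gene length reversed the mast cell, basophil and eosinophil odds ratio to 4.50. With 1 replicate left out, the promoter share ranged from 28.5% to 28.8%, the X to autosome ratio from 0.337 to 0.339 and the distal ratio of surface and granule genes from 1.47 to 1.55. The other reversals were not called. The promoter odds ratio of surface and granule genes, 0.87, became 1.54 against matched lists, 1.32 with the replicated-peaks list and 1.06 with a 1-kb window, and ranged from 0.949 to 1.07 with 1 replicate left out. For T and NK cell genes it became 1.34 against matched lists and 1.30 with the replicated-peaks list, with 0.776 to 1.14 when 1 replicate was left out, and for B cell genes 1.59 against matched lists. For erythroid genes it became 0.456 with the IDR lists, 0.913 with the conservative list and 0.675 with the 5′ end, and for stem and progenitor genes 0.888 with the IDR lists. The distal ratio of endothelial genes became 0.855 with the IDR lists, 0.867 with the replicated-peaks list, 0.986 with reciprocal overlap, 0.944 with a 100-kb window and 0.95 to 0.989 with 1 replicate left out. That of stem and progenitor genes became 0.769 with the IDR lists, 0.931 with the conservative list and 0.994 for peaks of at least 4-fold, and that of erythroid genes 0.968 with the IDR lists and 0.980 with a 20-kb window. The HNF1 ratio became 1.25 against windows matched on GC content. The cause was not tested for any of these. Depth is unknown, so a region missing from a list was not shown to be closed. No paired analysis was possible because the series holds 1 group.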

Other observations

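Motif frequencies by strength and by region class were compared only after the distal motif results were seen. From the weakest to the strongest quartile of distal regions (12180 each), the GATA motif went from 28.0% to 22.1% of summits and the GATA/E-box composite from 1.58% to 0.747%. The PU.1 motif went from 0.583% to 1.14% and CTCF from 2.96% to 9.25%. These trends were not tested. At promoter summits NRF1 motifs were 17.1-fold and KLF/SP motifs 1.97-fold as frequent as at distal summits (Fisher exact p = 4.35e-68 and 6.04e-235, adjusted over 19 motifs), and GATA motifs 0.549-fold (p = 1.55e-262). Neither the quartiles nor the 2 classes of region were matched on GC content, so a part of base composition in these differences was not tested.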
